A study of Homo sapiens with 12 samples.

How the data were processed

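Gene expression was measured by stranded mRNA sequencing in 23132/87, an established gastric adenocarcinoma cell line, and SW48, an established colorectal adenocarcinoma cell line. Per the labels, cells of each line received 10 µM myricone C, described in the series title as a neolignan from Myristica fragrans, or the vehicle, 0.1% DMSO, for 48 h, with 3 biological replicates per group and 12 libraries in all. Libraries were made with a TruSeq Stranded mRNA kit, per the labels' protocols. FastQC and STAR, without versions, and the genome build GRCh38 are named in the submitters' processing notes. The counting tool, its strand setting, the annotation and the unit of the values are not given in the sources used here.

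The authors deposited a table of expression signal per gene for each line, with gene symbols and Ensembl gene identifiers. From the values, this deposited signal resembles FPKM or TPM, that is, a value scaled to library size and gene length, and which of these it is could not be settled. The values are not counts and show no steps of whole reads, so read depth is unknown and no counting interval is given. The listed values of a library sum to between 464037 and 536594. Every listed gene lies above 1 in all 6 libraries of its line or, at the lowest, at 1. Genes low or silent in either condition are therefore not listed, and a gene switched fully on or off would be missed. Mitochondrially encoded genes are not listed, while 15 mitochondrial pseudogenes in the 23132/87 table and 16 in the SW48 table take between 13.4% and 18.1% of each library's summed values. The tables were filtered separately and hold 11070 genes for 23132/87 and 11554 for SW48, with 10264 in both.

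The test fixed for counts did not apply to these values, so the test fixed for normalized values was used. Values were log2 transformed after adding a pseudocount of 1, genes with a mean of at least 1 were kept, and limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend and Benjamini-Hochberg adjustment, with a threshold of adjusted p under 0.05. All listed genes passed the filter. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and errors of fold changes are limma's moderated standard errors. Each line was fitted on its own 6 libraries without covariates. The difference between lines was the line-by-treatment term fitted on all 12 libraries, over the genes in both tables, and is given as the SW48 change minus the 23132/87 change. Genes called in the same direction in both lines were compared with the number expected for independent lists by Fisher's exact test across genes. Gene lists were tested with camera at a preset correlation between genes of 0.01, and the adjustment covered the lists with at least 3 listed members. Every adjusted p is from these limma fits. Camera with an estimated correlation and fry were alternatives.

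The 26 gene lists, the tests and the rule for naming genes were fixed before the data were examined. In each line the rule names the 4 genes with the largest rise and the 4 with the largest fall past the threshold with a mean of at least 10, and the 2 members of each list with the largest change past the threshold. For the difference between lines and for the shared response it names 4 genes in each direction at the same minimum mean, and ROCK1, ROCK2, DDIT3, ATF4 and HSPA5 are always named. Genes on the sex chromosomes from which sex could be inferred are never named. Some genes and a gene list covered by these rules are not reported here. Gene positions come from GENCODE release 29, on GRCh38, matched by Ensembl identifier. Transcript length and GC content came from the longest protein-coding transcript of each gene in the same release, which held 99.2% of the 23132/87 genes and 99.1% of the SW48 genes.

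The scripts were tested on simulated values drawn from the real means and spreads, with errors independent between genes. In each line 200 genes were changed, and the mitosis list was lowered by 1 on the log2 scale. Of genes changed by 0.5, 1 and 2 on the log2 scale, the 23132/87 fit on 11067 simulated genes recovered 29.8%, 80% and 98.6%, and 2.98% of its calls were unchanged genes. The SW48 fit on 11548 simulated genes recovered 15.5%, 75.3% and 98.2%, with 2.84% of calls unchanged genes. The fit of the difference on 10264 genes recovered 11.8%, 71.8% and 98.3%, with 5.13% of calls unchanged genes. Small differences were therefore often missed at that setting. In the real fits 46.5% of genes were called in 23132/87 and 29.3% in SW48, so the shares recovered there may differ. Small differences can still be missed in these data.

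Alternatives fixed beforehand were quantile normalization, limma without a trend, no filter and a stricter filter (at least 10 in at least 3 libraries), a fold threshold, pseudocounts of 0.1 and 5, all 12 libraries in one fit, the replicate number as a block, that block by the numbers in the SW48 column names, and leaving out each library in turn. Median-centred scaling was added after the data were seen, as were families of genes sharing a symbol stem. Loess fits on length and GC used a span of 0.5, and abundance-matched comparisons drew 10000 random lists from 200 ranks on either side. Figures were drawn with matplotlib 3.10.9.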

Results

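Transcript levels were measured in 23132/87 gastric and SW48 colorectal cancer cells exposed to 10 µM myricone C or vehicle for 48 h, with 3 libraries per group. The series title places the compound in relation to endoplasmic reticulum (ER) stress, apoptosis and ROCK, a kinase that controls actomyosin contraction. The design gives comparisons of myricone C against vehicle within each line, and of the response between the lines. No library duplicated another. The leading principal component separated treated from vehicle libraries in both lines and held 77.3% of the variance in 23132/87 and 68.7% in SW48. SW48 myricone C replicate 1 lay nearer the vehicle libraries than its partners did, at 14.4 on that component against 36.5 and 29.1, and 5.25% of its summed values came from 7SL and small nuclear RNA genes, against 0.0477% to 0.201% in the other SW48 libraries.

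In 23132/87 cells, the largest rise among genes named by the rule was that of CYP1A1, a xenobiotic-metabolising cytochrome P450, which went from 3.04 ± 0.985 to 205 ± 23.5 (SD, n = 3), a log2 change of 5.69 ± 0.17 (SE, adjusted p = 6.09e-08). DDIT3, which encodes the stress transcription factor CHOP, rose by 4.18 ± 0.19 (SE), ATF3, another stress-induced transcription factor, by 4.18 ± 0.26, and the haem-degrading enzyme HMOX1 by 3.97 ± 0.28. IGFL2 fell by 2.94 ± 0.20 on the log2 scale. The cell cycle transcription factor MYBL2 fell by 2.47 ± 0.12, the replicative helicase subunit MCM5 by 2.43 ± 0.12 and UHRF1, needed to maintain DNA methylation, by 2.40 ± 0.15 on the same scale. All libraries of each group lay apart for these genes. Across the 11070 genes listed for this line, 2582 rose and 2571 fell at adjusted p under 0.05 (limma), and 835 of them changed by at least 1 on the log2 scale.

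Stress genes rose together in 23132/87. Of 24 listed members of the integrated stress response, the programme driven by the transcription factor ATF4, 23 rose and 1 fell, with a median log2 change of 1.65 (camera adjusted p = 3.10e-16, and adjusted p = 0.0922 with an estimated correlation). ATF4 itself rose from 205 ± 16.4 to 470 ± 20.2 (SD, n = 3), a log2 change of 1.19. Among ER chaperones and genes of ER-associated degradation, 20 of 24 rose and 1 fell, with a median of 0.63 (adjusted p = 9.00e-08, and adjusted p = 0.372 with an estimated correlation). HERPUD1, an ER-associated degradation component, rose by 2.22 ± 0.17 (SE), the ER co-chaperone DNAJB9 by 2.07 ± 0.21 and HSPA5, the ER chaperone BiP, by 1.84 ± 0.17. NRF2 targets, which serve the antioxidant response, rose in 15 of 20 cases with none falling, at a median of 1.32 (adjusted p = 9.00e-08, and adjusted p = 0.246 with an estimated correlation), with SRXN1 at 2.38 ± 0.12 after HMOX1.

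Apoptosis genes in 23132/87 went both ways as lists while single members moved. Of 18 pro-apoptotic genes 5 rose and 5 fell (adjusted p = 0.609), with the death receptor gene TNFRSF10B up by 1.43 ± 0.11 (SE) and BBC3, which encodes PUMA, up by 1.28 ± 0.15. Of 8 anti-apoptotic genes 4 rose and 2 fell (adjusted p = 0.666). BIRC5, which encodes survivin and is also a mitotic gene, fell by 1.37 ± 0.12 on the log2 scale, and BIRC3 rose by 0.69 ± 0.20, a call that was lost without vehicle replicate 2 (0.61) or vehicle replicate 3 (0.62). Of 19 p53 targets 7 rose and 7 fell (adjusted p = 0.666), and those that rose included the secreted stress factor GDF15 at 2.12 ± 0.11 and the cell cycle inhibitor CDKN1A at 1.59 ± 0.16.

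Cell cycle genes fell throughout in this line. All 25 listed DNA replication genes fell, with a median log2 change of -1.88 (adjusted p = 1.17e-18, and adjusted p = 0.0872 with an estimated correlation), and cyclin E1 (CCNE1) went from 13.5 ± 1.41 to 1.60 ± 0.305 (SD, n = 3). All 23 mitosis genes fell, with a median of -0.98 (adjusted p = 8.96e-14, and adjusted p = 0.246 with an estimated correlation). Among them were ANLN at -1.49 ± 0.09 (SE) and the proliferation marker MKI67 at -1.33 ± 0.11. Cytosolic heat shock genes fell as well, 14 of 14, with a median of -1.48 (adjusted p = 1.74e-11, and adjusted p = 0.0872 with an estimated correlation). The list under that name also holds genes of mitochondrial chaperones, such as HSPE1. HSPA1A went from 225 ± 41.2 to 46.8 ± 7.36 and HSPB1 from 153 ± 29.1 to 31.5 ± 3.76 (SD, n = 3). HSPA1A has a near-identical neighbour, HSPA1B, with which reads can be shared, so its own level is uncertain. Of 7 listed WNT targets 6 fell and 1 rose, with a median of -1.19 (adjusted p = 0.0151, and adjusted p = 0.417 with an estimated correlation), and EPHB3 fell by 1.81 ± 0.21 and ZNRF3 by 1.35 ± 0.14 on the log2 scale. The WNT call was lost when genes had to reach 10 in at least 3 libraries (median -1.19).

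The transcripts of the kinases named in the series title showed no called change in 23132/87. ROCK1, at chromosome 18, 20946906 to 21111851 on GRCh38, was listed at 2.46 ± 0.322 with vehicle and 3.49 ± 0.651 with myricone C (SD, n = 3), a log2 change of 0.37 ± 0.15 (SE, adjusted p = 0.0651). ROCK2, at chromosome 2, 11179761 to 11348330, was at 12.4 ± 2.05 and 15.1 ± 0.960 (adjusted p = 0.117). The myosin light chain gene MYL9 was at -1.98 ± 0.38 (SE) and ARHGEF2 at 1.65 ± 0.11, each past the threshold. Of 15 listed targets of SRF or of its actin-sensing cofactor MRTF, 8 fell and 3 rose (adjusted p = 0.0731). Those that fell were ACTB, ACTG1, TPM1, TPM4, TAGLN, VCL, CNN2 and ACTN1, and those that rose were FHL2, FOS and EGR1. Members among these outside the naming rule were added after their values were seen. Beta-actin (ACTB) fell by 1.69 ± 0.15 and tropomyosin TPM1 by 1.28 ± 0.14 on the log2 scale. YAP-TAZ targets were not called as a list (3 of 12 rose and 2 fell, adjusted p = 0.807), although CCN2 fell by 2.32 ± 0.25 and GADD45A rose by 1.70 ± 0.13.

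Among metabolic and signalling lists in 23132/87, cholesterol synthesis and NF-kB targets were called as higher. Cholesterol synthesis and uptake genes rose in 14 of 25 cases and fell in 1, with a median log2 change of 0.51 (adjusted p = 0.000546, and adjusted p = 0.417 with an estimated correlation). Among them was CYP51A1 at 1.03 ± 0.12 (SE). NF-kB targets and cytokines rose in 7 of 10 cases with none falling, with a median of 0.78 (adjusted p = 0.0117, and adjusted p = 0.417 with an estimated correlation), among them RELB at 1.13 ± 0.12 and TNFAIP3 at 1.08 ± 0.22. Aryl hydrocarbon receptor targets did not pass as a list (3 of 4 rose and 1 fell, adjusted p = 0.0554), but beside CYP1A1 the gene TIPARP rose by 1.96 ± 0.13. Fatty acid synthesis (2 of 10 higher and 3 lower, adjusted p = 0.847), hypoxia and glycolysis (8 of 17 higher and 6 lower, adjusted p = 0.424), interferon-stimulated genes (3 of 10 higher and 1 lower, adjusted p = 0.424) and autophagy and lysosome genes (8 of 16 higher and 2 lower, adjusted p = 0.0832) were not called as lists. Their members included LPIN1 at 1.16 ± 0.14, ACSS2 at 0.81 ± 0.10, VEGFA at 2.18 ± 0.15, BNIP3L at 1.18 ± 0.12, IRF9 at 1.63 ± 0.19, IRF7 at 1.14 ± 0.14, GABARAPL1 at 2.06 ± 0.18 and SQSTM1 at 1.85 ± 0.12, each past the threshold. Intestinal differentiation genes (1 of 7 higher and 2 lower, adjusted p = 0.424) included CA2 at -1.78 ± 0.30 and the brush border protein VIL1 at -1.54 ± 0.18. Ribosome biogenesis genes (1 of 18 higher and 5 lower, adjusted p = 0.156) included UTP20 at -1.91 ± 0.12 and RRP12 at 0.73 ± 0.11.

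Of the lists of gastric epithelial, leukocyte and mesenchymal markers, only single members were listed in 23132/87. These were TFF1 among gastric epithelial markers, the lineage of this line, which fell by 0.85 ± 0.17 (SE) on the log2 scale, CD68 among leukocyte markers, a lysosomal protein gene that rose by 1.22 ± 0.16, and COL1A1 among mesenchymal markers, at -0.17 ± 0.15 and not called. In SW48 the only such marker listed was SNAI1, a mesenchymal transcription factor, at 0.23 ± 0.18 and not called. None of the 13 mitochondrially encoded transcripts was listed in either table. COL1A1 and SNAI1 lie outside the naming rule and were chosen after their values were seen. Adjusted over the list alone, other counts of changed members were found in 23132/87 for anti-apoptotic genes (7), p53 targets (15), interferon-stimulated genes (5) and ribosome biogenesis (5). For YAP-TAZ targets the median, 0.03, and the mean, -0.09, differed in sign.

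In SW48 cells the largest rises under the rule were those of DDIT4, an inhibitor of mTORC1 signalling, which went from 12.6 ± 1.04 to 393 ± 163 (SD, n = 3), a log2 change of 4.75 ± 0.26 (SE, adjusted p = 4.78e-06), and CHAC1, a glutathione-degrading enzyme, at 4.60 ± 0.25. DDIT3 rose by 4.55 ± 0.29 and NDRG1 by 3.81 ± 0.25. The largest falls were those of NOTUM, a secreted WNT antagonist, by 2.75 ± 0.39, ASB4 by 2.29 ± 0.28, the receptor phosphatase PTPRO by 2.26 ± 0.24 and ID3 by 1.94 ± 0.42 on the log2 scale. Across 11554 listed genes, 1170 rose and 2213 fell at adjusted p under 0.05 (limma), and 552 changed by at least 1. Risen genes made up 34.6% of the calls as deposited and 46.2% (1515 of 3280) after quantile normalization, and without myricone C replicate 2 the number called was 2199. Without myricone C replicate 1, the library nearest to vehicle, it was 3656.

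The stress programmes rose in SW48 too. All 24 listed integrated stress response genes rose, with a median log2 change of 1.86 (adjusted p = 5.14e-29, and adjusted p = 0.282 with an estimated correlation), and ATF4 went from 130.2 ± 3.03 to 474 ± 109 (SD, n = 3). Of 24 ER chaperone and ER-associated degradation genes 13 rose and 3 fell, with a median of 0.38 (adjusted p = 2.94e-05, and adjusted p = 0.361 with an estimated correlation). HERPUD1 rose by 2.03 ± 0.26 (SE), DNAJB9 by 1.86 ± 0.25 and HSPA5 by 1.84 ± 0.23. NRF2 targets rose in 11 of 15 cases and fell in 1, with a median of 1.17 (adjusted p = 4.04e-09, and adjusted p = 0.282 with an estimated correlation), with HMOX1 at 3.73 ± 0.27 and SRXN1 at 2.67 ± 0.23.

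Pro-apoptotic genes as a list were not called in SW48 (4 of 18 rose and 1 fell, adjusted p = 0.117). TNFRSF10B rose by 1.76 ± 0.20 (SE) and PMAIP1, which encodes NOXA, by 1.39 ± 0.24. Of 8 anti-apoptotic genes 2 rose and 1 fell (adjusted p = 0.809), with BIRC5 at -1.45 ± 0.13. XIAP was at 0.48 ± 0.14 (adjusted p = 0.0255), and that call was lost on leaving out vehicle replicate 1 (0.44) or 3 (0.43), or myricone C replicate 1 (0.45) or 2 (0.44). Of 20 p53 targets 4 rose and 4 fell (adjusted p = 0.845). GDF15 rose by 3.63 ± 0.42, and CDKN1A rose by 1.11 ± 0.32, a call that was lost without myricone C replicate 2 (0.98).

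All 23 mitosis genes fell in SW48, with a median log2 change of -1.07 (adjusted p = 1.58e-14, and adjusted p = 0.282 with an estimated correlation), among them NUSAP1 at -1.29 ± 0.12 (SE) and cyclin A2 (CCNA2) at -1.29 ± 0.12. Of 26 DNA replication genes 24 fell and none rose, with a median of -0.88 (adjusted p = 6.77e-11, and adjusted p = 0.341 with an estimated correlation), with thymidine kinase TK1 at -1.46 ± 0.14 and TYMS at -1.43 ± 0.23. Members of the cytosolic heat shock list fell in 9 of 14 cases and none rose, with a median of -0.47 (adjusted p = 0.00141, and adjusted p = 0.361 with an estimated correlation). Among them were HSPB1 at -1.22 ± 0.20 and HSPE1, which encodes a mitochondrial co-chaperone, at -0.99 ± 0.16. WNT targets were not called as a list (1 of 12 higher and 5 lower, adjusted p = 0.0794), with TNFRSF19 at -1.56 ± 0.22 beside NOTUM.

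Neither kinase gene was called in SW48. ROCK1 was at 11.0 ± 0.924 with vehicle and 13.1 ± 0.230 with myricone C (SD, n = 3, adjusted p = 0.189), and ROCK2 at 15.8 ± 1.67 and 15.0 ± 3.60 (adjusted p = 0.712). ARHGEF2 was at 2.41 ± 0.15 (SE) and cofilin (CFL1) at -1.03 ± 0.14, each past the threshold. Of 18 SRF-MRTF targets 4 rose and 3 fell (adjusted p = 0.117), with FOSB at 2.49 ± 0.25 and FHL2 at 2.04 ± 0.26. YAP-TAZ targets were called as higher (5 of 15 rose and 2 fell, median 0.15, adjusted p = 0.0436, and adjusted p = 0.282 with an estimated correlation), with IGFBP3 at 2.41 ± 0.35 and GADD45A at 1.88 ± 0.31. This call was lost after quantile normalization (median 0.23), after median-centred scaling (0.20) and without vehicle replicate 3 (0.07).

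Lipid synthesis lists were called as higher in SW48. Cholesterol synthesis and uptake genes rose in 12 of 25 cases and fell in 2, with a median log2 change of 0.38 (adjusted p = 7.01e-05, and adjusted p = 0.361 with an estimated correlation). The largest rise was that of INSIG1 at 2.36 ± 0.19 (SE). Fatty acid synthesis genes rose in 5 of 13 cases and fell in 1, with a median of 0.35 (adjusted p = 0.0151, and adjusted p = 0.361 with an estimated correlation), with the desaturase SCD at 1.38 ± 0.15 and LPIN1 at 1.11 ± 0.17. The fatty acid call was lost without myricone C replicate 1 (0.23) and with fry. Hypoxia and glycolysis genes rose in 8 of 18 cases with none falling, with a median of 0.31 (adjusted p = 0.00148, and adjusted p = 0.282 with an estimated correlation), led by NDRG1 and VEGFA at 2.86 ± 0.17. Aryl hydrocarbon receptor targets were called as higher (1 of 4 rose, median 0.52, adjusted p = 0.0436, and adjusted p = 0.282 with an estimated correlation) with TIPARP at 1.20 ± 0.13. NF-kB targets were called likewise (2 of 7 rose, median 0.22, adjusted p = 0.0436, and adjusted p = 0.282 with an estimated correlation) with RELB at 0.96 ± 0.19 and NFKB2 at 0.94 ± 0.15. Both calls were lost after median-centred scaling (0.57 and 0.27). The receptor list was also lost after quantile normalization (0.59) and without vehicle replicate 2 (0.37) or myricone C replicate 1 (0.23), and the NF-kB list under the stricter filter (0.10) and without vehicle replicate 3 (0.15) or myricone C replicate 2 (0.14).

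Interferon-stimulated genes (3 of 9 higher and 1 lower, adjusted p = 0.0501), autophagy and lysosome genes (3 of 18 higher and 4 lower, adjusted p = 0.617), intestinal differentiation genes (1 of 3 higher and 2 lower, adjusted p = 0.484) and ribosome biogenesis genes (2 of 18 higher and 1 lower, adjusted p = 0.0501) were not called as lists in SW48. Their members included IRF9 at 1.11 ± 0.16 (SE), IRF7 at 0.83 ± 0.20, SQSTM1 at 2.52 ± 0.25, MAP1LC3B at 1.47 ± 0.19, RRP12 at 0.85 ± 0.15 and the intestinal transcription factor CDX2 at -1.47 ± 0.18. CEACAM5 rose by 0.72 ± 0.18. RRP9 was at 0.47 ± 0.15 (adjusted p = 0.0330), a call lost without vehicle replicates 2 (0.33) or 3 (0.51) or myricone C replicates 2 (0.43) or 3 (0.44). Adjusted over the list alone, other counts of changed members were found in SW48 for ER chaperones (17), pro-apoptotic genes (6), YAP-TAZ targets (8), p53 targets (10), cholesterol synthesis (16), fatty acid synthesis (7), NRF2 targets (13) and hypoxia and glycolysis (9). For p53 targets and autophagy genes the medians (-0.13 and -0.07) and means (0.11 and 0.16) differed in sign, and for anti-apoptotic genes both lay under 0 while camera, which compares a list with all other genes, pointed up.

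**Figure D1:**
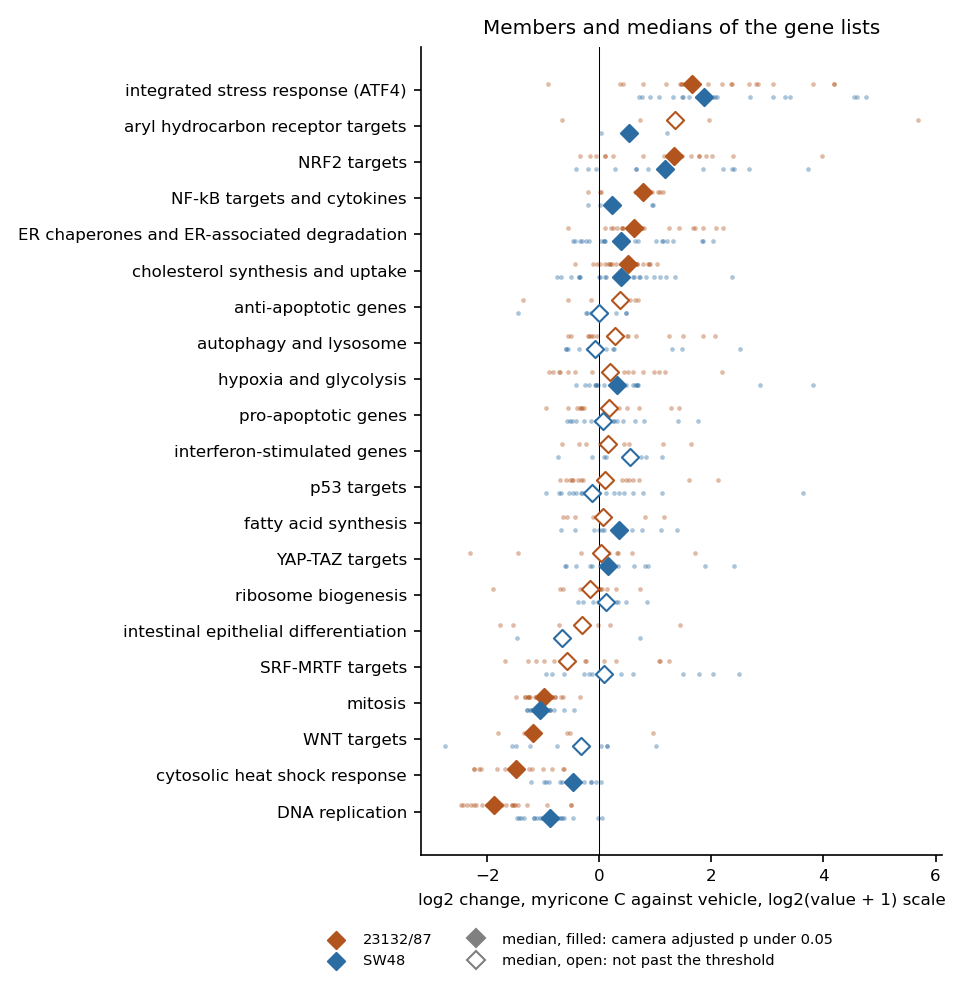
Log2 change of every listed member (small points) of tested gene lists in 23132/87 (orange) and SW48 (blue), on the log2(value + 1) scale, with each list's median as a diamond, filled where camera's adjusted p is under 0.05. Integrated stress response medians lie at 1.65 and 1.86, and DNA replication medians at -1.88 and -0.88.

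The lines shared much of the response. Among the 10264 genes in both tables, 734 rose in both lines where independent lists would share 244, and 1232 fell in both where 463 would be shared (one-sided Fisher's exact test across genes, p = 3.71e-258 for the rise and at or below 1e-300 for the fall). That test treats genes as independent units, so its p-values leave out the error between libraries and describe the overlap only. DDIT3 (chromosome 12, 57516588 to 57521737), CHAC1, HMOX1 and DDIT4 had the largest shared rises, with CHAC1 at 3.82 ± 0.13 (SE) in 23132/87. The histone chaperone gene ASF1B, MYBL2, the replication factor gene PCLAF and MCM5 had the largest shared falls, with ASF1B at -2.40 ± 0.12 and -1.58 ± 0.21 and PCLAF at -1.79 ± 0.14 and -1.81 ± 0.13 in 23132/87 and SW48. HSPA5 (chromosome 9, 125234853 to 125241330) rose by 1.84 in each line, with a difference of -0.01 ± 0.32. Log2 changes correlated across genes with Pearson's r of 0.634 and Spearman's rho of 0.607, where genes are not independent replicates. Genes called in opposite directions numbered 96, of which 55 rose in 23132/87 and 41 rose in SW48.

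**Figure D2:**
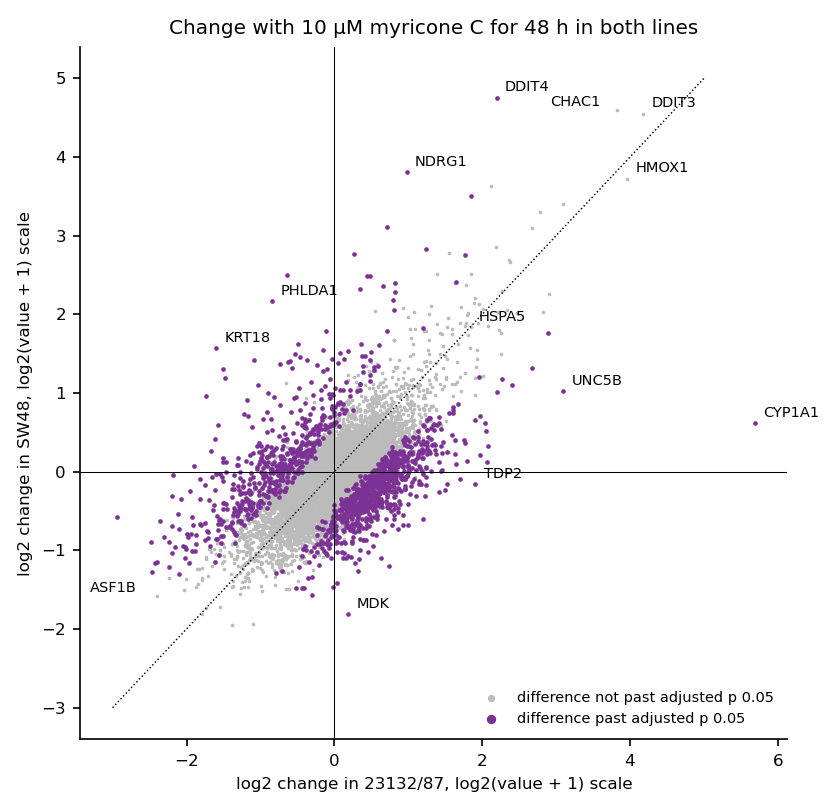
Log2 change with myricone C in 23132/87 (x axis) and SW48 (y axis), on the log2(value + 1) scale, for the 10264 genes in both tables, where the dotted line marks equal change. Purple points are the 1306 genes whose change differed between lines, CYP1A1 lies far to the right at 5.69 and 0.61, and KRT18 lies at -1.60 and 1.57, although its reads can be shared with pseudogenes.

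Whether the response itself differed between the lines was tested with the line-by-treatment term. CYP1A1 (chromosome 15, 74719542 to 74725610) differed most, since its level in SW48 was 2.77 ± 0.485 with vehicle and 5.17 ± 2.91 with myricone C (SD, n = 3), a difference in log2 change of -5.08 ± 0.36 (SE, adjusted p = 4.76e-06). KRT18, which encodes an epithelial keratin (chromosome 12, 52948871 to 52952901), fell from 3049 ± 388 to 1012 ± 196 in 23132/87 and rose from 448 ± 184 to 1263 ± 299.8 in SW48 (SD, n = 3), a difference of 3.17 ± 0.38 (adjusted p = 0.000273). KRT18 has near-identical pseudogenes that can share its reads, so its level is uncertain. PHLDA1 also fell in 23132/87, by 0.84 ± 0.09, and rose in SW48, by 2.16 ± 0.26. Its antisense partner PHLDA1-AS1 (chromosome 12, 76030494 to 76031378) lies within the PHLDA1 locus (76025447 to 76033932), and as the strand setting of the counting is not stated, reads of these genes cannot be told apart. NDRG1 rose further in SW48 (difference 2.83 ± 0.33), UNC5B further in 23132/87 (-2.07 ± 0.34), TDP2 rose by 1.91 ± 0.12 in 23132/87 with -0.15 ± 0.14 in SW48, and the growth factor gene MDK fell by 1.81 ± 0.16 in SW48 with 0.19 ± 0.26 in 23132/87.

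**Figure D3:**
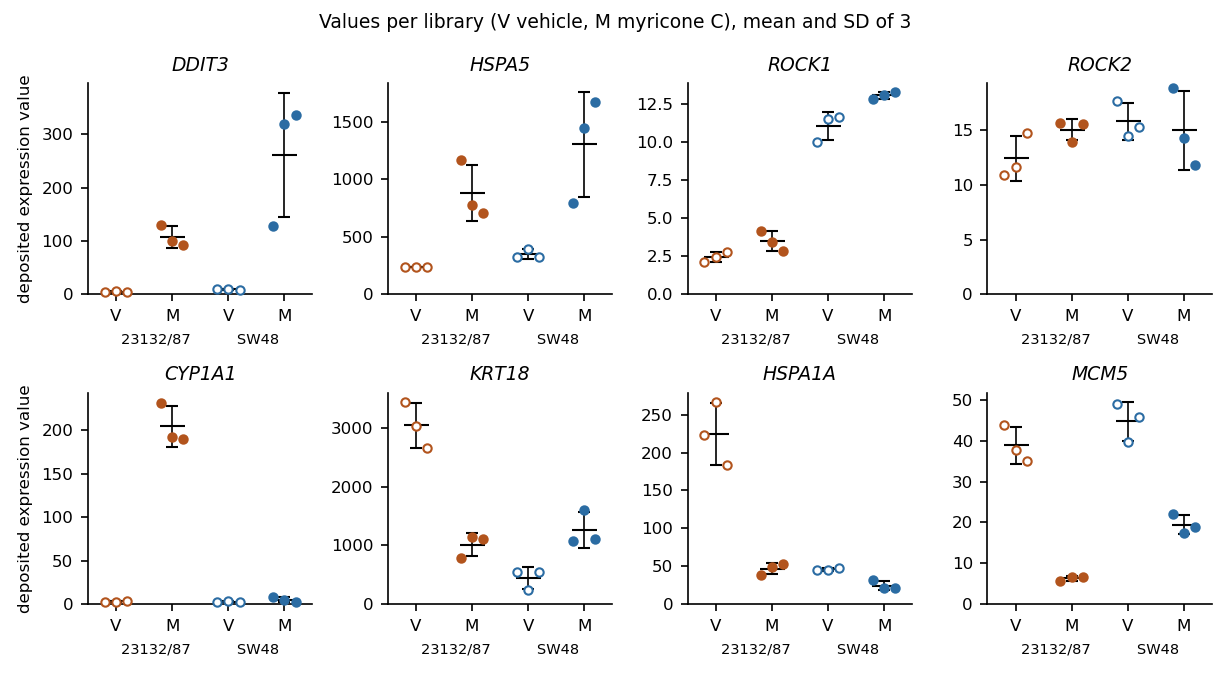
Deposited expression value per library (linear axes from 0) for 8 genes, with vehicle (V, open) and myricone C (M, filled) in 23132/87 (orange) and SW48 (blue), where bars mark the mean and SD of 3 libraries. ROCK1 and ROCK2 have no called change, and CYP1A1 reaches 205 in treated 23132/87 and 5.17 in treated SW48.

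Replication and heat shock genes fell further in 23132/87 than in SW48. The difference was positive and called for 15 of 25 DNA replication genes and negative for none (median 0.89, adjusted p = 3.59e-18, and adjusted p = 0.187 with an estimated correlation), and for 12 of 14 heat shock genes with none negative (median 0.91, adjusted p = 2.24e-15, and adjusted p = 0.103 with an estimated correlation). SRF-MRTF targets (6 of 15 positive, median 0.52, adjusted p = 2.48e-05, and adjusted p = 0.202 with an estimated correlation), hypoxia and glycolysis genes (5 of 17 positive and 1 negative, median 0.41, adjusted p = 0.00261, and adjusted p = 0.202 with an estimated correlation) and WNT targets (4 of 7 positive and 1 negative, median 0.71, adjusted p = 0.0123, and adjusted p = 0.217 with an estimated correlation) also had higher changes in SW48. So did the integrated stress response (4 of 23 positive, median 0.32, adjusted p = 0.000344, and adjusted p = 0.520 with an estimated correlation) and ribosome biogenesis (1 of 18 positive, median 0.21, adjusted p = 0.000846, and adjusted p = 0.520 with an estimated correlation). ER chaperones had lower changes in SW48 (1 of 24 positive and 5 negative, median -0.32, adjusted p = 0.0147, and adjusted p = 0.697 with an estimated correlation), a call lost without 23132/87 myricone C replicate 1 (-0.22), SW48 vehicle replicate 2 (-0.24) or SW48 myricone C replicate 1 (-0.26). With fry the calls of a difference for the integrated stress response, ribosome biogenesis and ER chaperones were lost. The WNT difference covers only 7 of the 12 members listed in SW48. It leaves out NOTUM, the largest fall under the rule in SW48, which was not listed in 23132/87.

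No call for the difference was made for 13 lists, including mitosis genes (median 0.00264, adjusted p = 0.739) and NRF2 targets (median 0.08, adjusted p = 0.789). Camera pointed up for anti-apoptotic genes and p53 targets, whose medians were -0.09 and -0.01, and for mitosis genes, whose mean was -0.02. Adjusted over the list alone, the difference was called for 20 of 25 replication genes, 14 of 14 heat shock genes, 8 of 15 SRF-MRTF targets, 9 of 17 hypoxia genes, 5 of 7 WNT targets, 4 of 23 integrated stress response genes, 6 of 24 ER chaperones and 3 of 18 ribosome biogenesis genes. In total 1306 genes had a called difference, 547 with the higher change in SW48 and 759 with the higher change in 23132/87 (limma). Positive differences made up 41.9% as deposited, 54.5% after quantile normalization and 54.1% after median-centred scaling, so the balance of directions depends on the scaling. Without SW48 vehicle replicate 2 the number called was 830.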

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

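The tests of the spread between SW48 libraries, of the size of changes in SW48 and of an overall stronger response in 23132/87, and the splits of the line labels, were chosen after the results they measure were seen, and the other tests in this part before. Of 74 named genes in both tables, 29 had a change that differed between the lines by the line-by-treatment term in limma, 21 with the higher change in SW48 and 8 with the higher change in 23132/87. The naming rule took the 4 largest differences in each direction from these same data, so those genes count by construction. Most other named genes were picked for large changes within a line. Among all 10264 genes in both tables, 1306 (12.7%) had a called difference. The share among named genes therefore says nothing about genes in general. Differences are given as the SW48 log2 change minus the 23132/87 log2 change.

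KRT18 (3.17), PHLDA1-AS1 (3.14), PHLDA1 (3.01), NDRG1 (2.83), DDIT4 (2.56) and IGFL2 (2.36) had the largest positive differences. Positive differences above 1 were also found for UTP20 (1.98), INSIG1 (1.70), CCNE1 (1.58), EPHB3 (1.47), HSPA1A (1.34), SCD (1.32), MCM5 (1.27), UHRF1 (1.26), MYBL2 (1.19), ZNRF3 (1.13) and HSPB1 (1.02). Smaller positive differences were those of ARHGEF2 (0.76), ACTB (0.73), TPM1 (0.65) and ATF4 (0.64). CYP1A1 (-5.08), UNC5B (-2.07), TDP2 (-2.06), MDK (-1.998), GABARAPL1 (-1.94), CDX2 (-1.45), TIPARP (-0.76) and NUSAP1 (-0.50) had negative differences. PHLDA1 and its antisense partner overlap, and HSPA1A, KRT18 and ACTB have near-identical copies or pseudogenes, so the levels of these genes are uncertain.

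Gene lists with a called difference included DNA replication (median 0.89), cytosolic heat shock (0.91), WNT targets (0.71), SRF-MRTF targets (0.52), hypoxia and glycolysis (0.41), the integrated stress response (0.32), ribosome biogenesis (0.21) and, with the lower change in SW48, ER chaperones (-0.32). With an estimated correlation camera called 0 lists, with 5 at an unadjusted p under 0.05, while fry called 8 lists. Of 100 splits of the line labels within vehicle and within treated libraries, made after each gene's line means were removed, 10 gave at least 9 lists with a difference and the highest other split gave 9, so chance was not excluded for the number of lists.

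For genes, only the real one of these splits (1 of 100) gave as many as the 1306 called differences, and the highest other gave 3. This share lies under 0.05. However, the other splits mix libraries of both lines or exchange the treated ones. That puts the difference between lines into their residual spread or cancels it, so their low counts do not exclude chance. Splits of the treatment labels within lines, fixed beforehand, decide nothing about the difference, since the treatment effect enters it. The highest of them called 5423 genes and exchanged treated and vehicle libraries in SW48 alone. For genes called the same way in both lines, the real 1966 were the highest of 100 splits of the treatment labels (1 of 100), and the highest other split gave 96. These 96 are the genes called in opposite directions, from the split that exchanged the SW48 libraries alone, and give no chance level. The remaining splits mix treated and vehicle libraries, which puts the treatment effect into their residual spread. The comparison therefore says little about chance. Within a line, 10 splits are too few for a share under 0.05. There the real split called 5153 genes in 23132/87 and 3383 in SW48 against a highest other of 0 in each (1 of 10 in each), and 9 and 12 lists against highest others of 8 and 10 (1 of 10 in each).

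Fewer genes were called in SW48 than in 23132/87. A single SW48 library, myricone C replicate 1, had a slope on the 23132/87 changes of 0.449 against 0.654 and 0.641. It did not account for the whole gap, since 3656 genes were called without it. The lowest 23132/87 count with a myricone C library left out was 4276. Leaving out SW48 myricone C replicate 1 raised the SW48 count from 3383 despite fewer samples, so a part of the gap may rest on that library. Smaller changes in SW48 may account for the lower count and stay open. Over the 10264 genes in both tables the SD of log2 changes, with the error variance removed, was 0.84 times that in 23132/87 (95% bootstrap interval over genes 0.82 to 0.87). Without that library it was 0.95 times, which lies outside the interval. The interval leaves out the error between libraries. A larger spread between SW48 libraries cannot be told apart either, since the median residual SD was 1.09 times that in 23132/87, between the bounds set for and against it, and 1.02 times without that library, where the count rose from 3383 to 3656. A difference between the lines themselves stays open and was not tested.

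Heat shock genes fell in both lines by camera at the preset correlation, calls lost with an estimated correlation (adjusted p = 0.0872 in 23132/87 and adjusted p = 0.361 in SW48). Bias from transcript length or GC content was argued against as the whole cause, since the list's median was -1.56 in 23132/87 (from -1.48) and -0.42 in SW48 (from -0.47, adjusted p = 0.00152 after at the preset correlation) once a loess trend on both was removed. In 23132/87 a general fall of abundant transcripts was argued against too, as the median lay at percentile 0 of 10000 random lists matched on vehicle level, whose lowest was -0.92. In SW48 the median lay at percentile 2.68, so a general fall of abundant transcripts may account for the SW48 fall and stays open.

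Replication genes and heat shock genes fell further in 23132/87. The library that responded less was argued against as the whole cause, since without it the median differences were 0.84 (from 0.89) for replication and 0.91 (0.91 with it) for heat shock, with camera adjusted p of 1.77e-14 and 2.02e-13. A generally stronger response in 23132/87 was argued against as the whole cause for replication. The mitosis list differed by a median of 0.00264 (95% bootstrap interval over genes -0.06 to 0.06). This interval leaves out the error between libraries, which gave single differences SEs such as 0.25 (MKI67) and 0.15 (CCNA2). The argument is therefore weaker than the interval alone would make it. The SD of changes over all genes was smaller in SW48 (ratio 0.84, and 0.95 without SW48 myricone C replicate 1), and a part of the difference stays open. A candidate explanation is that the lines differ in how far replication genes, but not mitosis genes, follow the compound, which is a hypothesis found and tested on the same data. None of these list differences held with an estimated correlation.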

How the results depend on the processing

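Median-centred scaling and the values per list were chosen after the data were seen, and all other alternatives before. No called named gene turned its sign and no called list the direction of its test, although uncalled ones did, and most called differences were negative as deposited (759 of 1306) and positive after quantile normalization (666 of 1223) and median-centred scaling (686 of 1269). Among named genes, 1862 of 1880 alternatives stayed on the same side of the threshold, 14 lost the call and 4 gained it. These include the setting without a filter, which could change nothing. The rule picked large changes from these same data, with 116 of 120 results called, so a high share was likely from the start. Among lists tested with camera at the preset correlation, 744 of 789 alternatives stayed on the same side, 25 lost it and 20 gained it.

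Requiring a log2 change of at least 1 left 835 genes in 23132/87, 552 in SW48, 371 for the difference and 230 changed the same way in both, by its construction. With an estimated correlation 0 lists were called in 23132/87, 0 in SW48 and 0 for the difference by camera, with 3, 3 and 5 at an unadjusted p under 0.05, while fry called 18, 13 and 8 and lost the calls of fatty acid synthesis in SW48 and of the differences for the integrated stress response, ER chaperones and ribosome biogenesis. Fry asks whether a list's members changed at all, while camera compares them with all other genes, so their counts answer different questions. The cause of the shift within camera was not tested. Leaving out each library in turn, with fewer samples, gave 3959 to 4888 genes in 23132/87, 2199 (without myricone C replicate 2) to 3656 in SW48, 830 (without SW48 vehicle replicate 2) to 1412 for the difference and 1422 to 2061 shared, and 9 to 10, 11 to 14 and 7 to 10 lists. The main filter on low values removed no gene, so leaving it out tests nothing. Count-based tests were not run, as the values are not counts. Read depth is unknown, so what it limits could not be given.

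The replicate numbers did not pair the libraries: deviations of same-numbered vehicle and treated libraries correlated at -0.24, 0.11 and -0.27 in 23132/87 and -0.07, -0.18 and -0.14 in SW48. With the replicate number as a block, 770 genes had a called difference instead of 1306, and RRP9 in SW48 lost its call. The cause was not tested. By the numbers in the SW48 column names, only 2 pairs could be compared (0.15 and 0.27). Each was the highest correlation of its vehicle library, so pairing by those numbers was not excluded. The block by column names took the calls of XIAP and CEACAM5 in SW48.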

Other observations

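The gene families in this part were defined by shared gene symbols after the data were seen, and all tests on them were chosen then. Of 17 families, camera called 8 in 23132/87, 11 in SW48 and 7 for the difference, and 0 with an estimated correlation. Only some of them are described. Mitochondrial ribosomal proteins (lower) and zinc finger proteins (higher), for example, were also called in both lines. In SW48, however, 25 of 269 zinc finger genes rose and 21 fell (median 0.03, camera adjusted p = 0.0499). That call was lost after quantile normalization (median 0.08, camera adjusted p = 0.0624). Tubulin genes fell in 10 of 12 cases in 23132/87 (median log2 change -1.09, camera adjusted p = 7.52e-06, and adjusted p = 0.327 with an estimated correlation) and in 8 of 11 in SW48 (median -0.56, adjusted p = 0.000969, and adjusted p = 0.575 with an estimated correlation). TUBA1B fell by 1.71 ± 0.11 (SE) in 23132/87 and fell by 1.33 ± 0.12 in SW48 on the log2 scale. Tubulin genes are similar enough to share reads, so single members are uncertain. Subunits of the CCT chaperonin, which folds tubulin and actin, fell in 8 of 8 cases in 23132/87 (median -0.79, adjusted p = 1.27e-05, and adjusted p = 0.239 with an estimated correlation) and none was called in SW48 (median -0.20, adjusted p = 0.325). The difference between lines was called for 6 of 8 CCT subunits (median 0.66, adjusted p = 1.75e-07, and adjusted p = 0.391 with an estimated correlation). Tubulins and the CCT difference kept direction and call under quantile normalization and median-centred scaling.

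Subunits of respiratory complex I fell in 29 of 37 cases in 23132/87 and rose in 1 (median -0.57, adjusted p = 1.27e-06, and adjusted p = 0.465 with an estimated correlation), and fell in 32 of 37 in SW48 (median -0.69, adjusted p = 3.86e-13, and adjusted p = 0.575 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, rose in 13 of 20 cases and fell in 2 in 23132/87 (median 0.69, adjusted p = 0.000225, and adjusted p = 0.327 with an estimated correlation), and rose in 12 of 20 in SW48 (median 0.93, adjusted p = 7.87e-10, and adjusted p = 0.575 with an estimated correlation). Both families kept direction and call under both scalings. The integrated stress response list also holds synthetase genes (AARS1, GARS1, WARS1 and EPRS1), so the synthetase rise is not a separate observation. Keratins were called as higher in SW48 (5 of 6 rose, median 1.35, adjusted p = 0.00142, and adjusted p = 0.591 with an estimated correlation), with KRT16 at 3.11 ± 0.32 (SE) and KRT8 at 1.19 ± 0.26, while in 23132/87 the family was not called (3 of 9 fell and 1 rose, median -0.08, adjusted p = 0.292) and KRT8 fell by 1.48 ± 0.19 and KRT19 by 1.23 ± 0.21 on the log2 scale. The difference for KRT8 was 2.67 ± 0.35, and keratin pseudogenes can share these reads. The keratin calls in SW48 and for the difference (median 1.96, adjusted p = 0.00101, and adjusted p = 0.437 with an estimated correlation) held under both scalings. KRT16, KRT8, KRT19 and TUBA1B were chosen after their values were seen. Proteasome subunits fell in 12 of 37 cases and rose in 1 in 23132/87 (median -0.17, adjusted p = 0.00348, and adjusted p = 0.417 with an estimated correlation), a call lost after quantile normalization (median -0.04, adjusted p = 0.197) and held after median-centred scaling (median -0.20, adjusted p = 0.00214). In SW48 they fell in 13 of 37 cases and none rose (median -0.29, adjusted p = 0.000561, and adjusted p = 0.591 with an estimated correlation), a call that held after quantile normalization (median -0.17, adjusted p = 0.00692) and median-centred scaling (median -0.24, adjusted p = 0.000878).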
